A study of Drosophila melanogaster with 2 samples.

How the data were processed

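The data were 2 polyA RNA-seq libraries from larval brains of Drosophila melanogaster, 1 control and 1 brat RNAi. Per the labels' protocols, animals were raised at 18 °C and shifted to 29 °C, and brains were dissected 24 h after the shift. The cells, type II neuroblasts (neural stem cells) and their 24 h progeny, carried a membrane-bound GFP and were collected by fluorescence-activated sorting. Both crosses carried a Dicer-2 transgene and a temperature-sensitive Gal80, which holds the RNAi off at the lower temperature.

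The authors deposited counts of read pairs per gene for each library, and 1 table that compares them. Per the submitters' processing notes, the tools used were BWA 0.6.1, TopHat 1.4.1, HTSeq and DESeq 1.8.3; the role of each, the genome build and the strand setting of the counting are not given in the sources used here. In the authors' deposited table, the base means are normalised counts (a signal that is never negative), per the file headers. In that table the authors also gave a log2 fold change of control over brat RNAi, turned round here, and an adjusted p-value, per the file headers. Dividing the deposited counts by median-of-ratios size factors gave those base means, and all 10987 finite log2 values equalled those computed here within 1e-06.

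The count tables held 14284 genes, 12401 of them with a count in either library. Gene counts summed to 16566265 in the control and 15236504 in the brat RNAi library. The 5 categories of read pairs assigned to no single gene stayed out of all sums and ratios. They held 22.7% of the control table and 27.2% of the brat RNAi table, nearly all of it pairs assigned to no annotated feature. The counts do not show whether those pairs lay between genes or inside them, for example in introns. The size factors were 1.09 for the control and 0.913 for the brat RNAi library. A count of 0 was replaced by a floor of 3 counts per library to give a fold written as at least; the upper limit of the counting interval, which is 2-sided, lies slightly closer to 0.

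For each gene the log2 ratio of brat RNAi over control was computed from the counts divided by the size factors. Each ratio has a 95% exact (Clopper-Pearson) counting interval, printed in parentheses for the main genes and those with the fewest counts and otherwise left out for brevity. Read pairs were not counted as molecules, so intervals and bounds cover counting error only. With 1 library per group there are no residual degrees of freedom, so no test was run and no p-value was computed across genes. The 9142 genes with counts summing to at least 20 are called measured. A gene was counted as at least 2-fold higher or lower when its log2 ratio was at least 1 in size and its interval excluded 0.

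Gene lists were described by the median log2 ratio of their measured members, with a counting interval from 2000 Poisson draws. The percentile of that median was taken among 10000 random lists of the same size, matched on mean level in 20 bins, as a description of these libraries. The measure, the thresholds, 29 lists, the rule for naming genes and most alternatives were fixed before the data were examined. Another 4 lists (yolk, eggshell and female germline; ring gland; neuropeptides; ecdysone response) were made after the values were seen. The rule named brat, dpn and zld, and always dm, klu, N, cherub, pros, erm, elav and repo. It added the 10 highest and 10 lowest ratios among genes at least 2-fold apart with a mean normalised count of at least 100. From each list it took up to 4 measured members at least 2-fold apart with the largest ratios, or the 2 most abundant measured members where fewer than 2 were that far apart. Where a list had a single member at least 2-fold apart (grh, foxo, so, skl, He and vvl), that gene was named after its value was seen, as were Hey, HLHm3, HLHm5, Mlc2, Tm2, the genes of the last part of the closing section and the exceptions given there and among the results looked at more closely.

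Gene symbols are those of the authors' deposited table, with current names from the reference annotation, BDGP6, which matched 13642 of the gene identifiers. The build behind the counts is not given, so no coordinates are printed, and the annotation served only for names, gene order and transcript lengths. A median transcript length was found for 8896 measured genes (97.3%), of which 202 were matched by symbol. After the values were seen, ratios were also corrected by subtracting the median of genes in the same decile of length and of level. On Poisson counts simulated for 9131 genes, 95.8% of intervals of unchanged genes held 0 and 0.392% of unchanged genes were counted as 2-fold. These simulated libraries had counting error alone, with no other spread between them and no trend with length or level. Their shares therefore check the computation and are not error rates for the real libraries. All of the genes simulated at a log2 ratio of 3 were recovered, and 97% of those at 1.5. Alternatives were edgeR's TMM factors, total count and upper quartile scaling, pseudocounts, other count filters and thresholds, the authors' fold changes, and other ways of matching the random lists. Computations used Python 3.11.15 with numpy 2.4.6, pandas 2.3.3 and scipy 1.17.1, and R 4.3.3 with edgeR 4.0.16 for scaling factors alone.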

Results

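Brat is a translational repressor of the TRIM-NHL family whose loss turns type II neuroblast lineages of the fly brain into tumours. The study compared sorted type II lineages with and without brat RNAi, and its title names the transcription factors Deadpan and Zelda as what Brat inhibits. Each group was 1 library, with 16566265 gene counts in the control and 15236504 in the brat RNAi library. No difference below has a replicate check, and each describes these libraries rather than the genotypes.

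The targeted gene, brat (FBgn0010300), was lower in the brat RNAi library, with a log2 ratio of -0.69 (-0.73 to -0.65). Its counts were 12210 in the control and 6312 in the brat RNAi library, which after normalisation is 38.0% lower. After correction for transcript length and level its log2 ratio was -1.15. The direction matched the labels. Any reads of the hairpin itself would be counted with the gene and were not separated from it.

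Both genes of the study's title had higher mRNA in the brat RNAi library. An mRNA ratio does not measure translational repression. In these libraries an effect of Brat on either gene cannot be told from a different mix of sorted cells. Deadpan (dpn, FBgn0010109), a basic helix-loop-helix repressor of neuroblasts, had a log2 ratio of 0.98 (0.90 to 1.06) and counts of 2081 and 3416. Zelda (zld, listed as vfl, FBgn0259789), a zinc finger activator best known from the early embryo, had 0.85 (0.81 to 0.89) and counts of 8068 and 12161. Neither reached the 2-fold threshold. Myc (dm), a growth regulator, was 2.20-fold higher at 1.14 (1.06 to 1.22). The stem cell factor klu was at 0.62 (0.55 to 0.69) and the receptor Notch (N) at 0.77 (0.73 to 0.82). The long noncoding RNA cherub (CR43283) took 2.66% of gene counts in the control and 3.45% in the brat RNAi library, a log2 ratio of 0.52 (0.51 to 0.52). After correction for length and level, dpn was at 0.83, zld at 0.40 and Myc at 0.76. The same correction put klu at 0.29, N at 0.32 and cherub at 0.17.

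The 4 markers of differentiation fixed beforehand lay near 0. The log2 ratio was 0.18 (0.14 to 0.23) for pros, which ends self-renewal in daughter cells, and -0.05 (-0.12 to 0.02) for erm, a factor of intermediate progenitors. It was -0.12 (-0.20 to -0.04) for the neuronal gene elav and -0.09 (-0.47 to 0.28) for the glial gene repo. After correction for transcript length and level, pros stood at -0.27, erm at -0.28 and elav at -0.26. Hey, a gene of newborn neurons named after its value was seen, was lower at -0.99 (-1.29 to -0.69).

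Over all measured genes, 105 were at least 2-fold higher and 410 at least 2-fold lower in the brat RNAi library, while 7487 (81.9%) lay within 1.5-fold. The lower genes were mostly scarce ones. Below a mean normalised count of 100 there were 54 higher and 373 lower genes, and at or above it there were 51 higher and 37 lower. With total count scaling the share of higher genes was 10.4% in place of 20.4%. After correction for transcript length and level, with 188 higher and 237 lower genes, it was 44.2%. That correction subtracts the median of genes of similar length and level, so it partly evens out higher and lower genes by construction. It would also remove a real difference that such genes share.

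**Figure D1:**
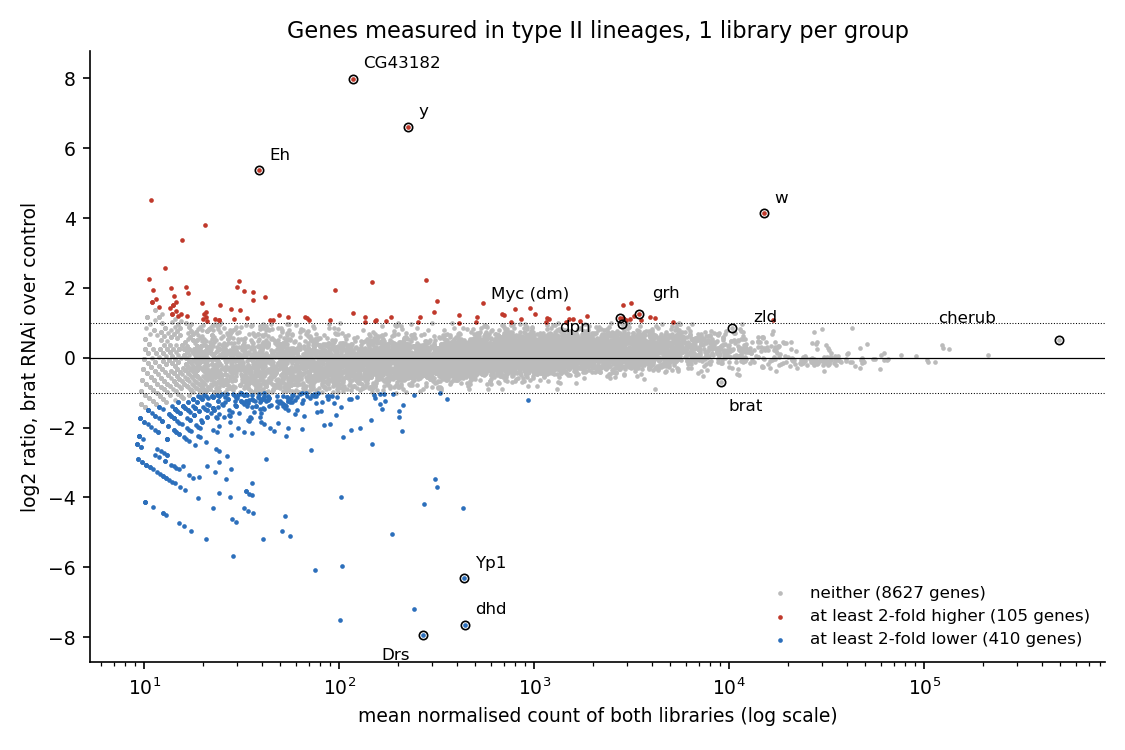
Each point is 1 of the 9142 measured genes, placed by its mean normalised count (x axis, log scale) and its log2 ratio of brat RNAi over control (y axis), with dotted lines at 2-fold. The 105 higher genes are red and the 410 lower genes blue. Most blue points lie at low counts. Of the labelled genes, CG43182, y, Eh and w lie highest and Drs, dhd and Yp1 lowest.

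Of the genes with a mean normalised count of at least 100, the highest ratios belonged to 2 pigmentation marker genes and a neighbour. CG43182 had 1 count in the control and 213 in the brat RNAi library, a 255-fold difference (log2 interval 5.50 to 13.31), and yellow (y) had 5 and 409 (6.62, 5.38 to 8.25). The eye colour gene white (w) had 1776 and 25973 (4.13, 4.06 to 4.20). CG6426 followed at 2.23, Hsp70Ab at 2.17, the acetylcholine receptor subunit nAcRalpha-34E at 1.62 and lama at 1.56. Hsp70Ab has near-identical copies that can share reads, so its value is uncertain. CG16879 at 1.58 and CG17341 at 1.51 are parts of 1 gene in the current annotation. Eip93F, an ecdysone-induced factor of late temporal identity, was at 1.42 (1.31 to 1.54).

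Neuroblast genes as a group were higher in the brat RNAi library. The 20 measured neuroblast factors had a median log2 ratio of 0.43 (0.39 to 0.45), at the 99.9th percentile of random lists, with 15 of 20 above 0. One member, grainyhead (grh), which keeps neuroblasts dividing, was at least 2-fold higher at 1.25. The most abundant members were mira, a carrier of fate determinants, at 0.44 and nab at 0.04. Against random lists matched on transcript length as well, the percentile was 99.8. After correction for length and level the median was 0.13 and grh was at 0.90, under 2-fold. The 8 type II factors had a median of 0.41 (0.34 to 0.47, percentile 96.8) and 0.25 after correction (percentile 93.5 with matching on length), with none 2-fold apart; their most abundant members were zld and Sp1, the latter at -0.02. The 11 intermediate progenitor factors had 0.16 (0.07 to 0.22, percentile 74.98), and -0.05 after correction, with grh as the member at least 2-fold apart and erm and ham (0.16) as the most abundant. The 10 genes of ganglion mother cells and newborn neurons had 0.04 (-0.02 to 0.10, percentile 25.2), with none 2-fold apart, and lola at 0.21. Matching on length as well put this last list at the 2.14th percentile, and its corrected median was -0.23.

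Ribosome biogenesis genes were also higher as a group. Their 39 measured members had a median of 0.40 (0.37 to 0.45), above every one of the 10000 random lists, and 37 of them were above 0. Myc, fixed in this list, was the member at least 2-fold apart; among the most abundant members, the pseudouridine synthase Nop60B was at 0.72 and CG8801 at -0.04. The median was 0.39 after correction for length and level. The 18 genes of growth signalling had a median of 0.32 (0.26 to 0.36, percentile 99.5), with foxo at least 2-fold higher (1.16), Tor at 0.31 and eIF-4E at 0.08. Matching on length lowered that percentile to 94.3, and the corrected median was 0.11. The 35 S phase genes had 0.26 (0.17 to 0.28, percentile 95.8) and the 41 mitosis genes 0.26 (0.24 to 0.31, percentile 94.5), with none 2-fold apart in either. Their abundant members mus209 (PCNA), Mcm7, Top2 and CycA were at 0.13, 0.27, 0.40 and 0.25. With matching on length the S phase list stood at 99.3 and the mitosis list at 91.3, and their medians after correction for length and level were 0.10 and 0.08.

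Oxidative phosphorylation genes were slightly lower. The 32 members had a median of -0.16 (-0.17 to -0.13), below every random list, but none was 2-fold apart, and blw and ATPsyn-beta were at 0.03 and -0.12. Matched on length too, this list lay at the 5.20th percentile of random lists whose medians centred on -0.08, and its corrected median was also -0.08. Glycolysis genes, 14 in number, had a median of 0.07 (percentile 19.96), with Gapdh2 at 0.04 and Eno at -0.03.

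Notch targets of the Enhancer of split and Bearded families were lower in the brat RNAi library. The list of 18 Notch targets had a median of -0.67 (-0.83 to -0.51), below every random list, and 6 members were at least 2-fold lower. These included m4 at -1.35 (-1.67 to -1.03), Ocho at -1.24 (-1.60 to -0.90), HLHmbeta at -1.22 (-1.37 to -1.07) and Brd at -1.19 (-1.95 to -0.48). After correction for length and level the median was -0.45; m4, Ocho and HLHmbeta stayed beyond 2-fold, while Brd (-0.72), HLHm3 (-0.86) and HLHm5 (-0.73) did not. All 14 members of both families were below 0 with their intervals, while dpn and klu, fixed in the same list, were above 0. The 15 genes of the Notch pathway itself had a median of 0.26 (0.18 to 0.29, percentile 90.2), with none 2-fold apart; N and nej (0.61) were the most abundant. Its median was -0.07 after correction for length and level, at the 49.5th percentile with matching on length.

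**Figure D2:**
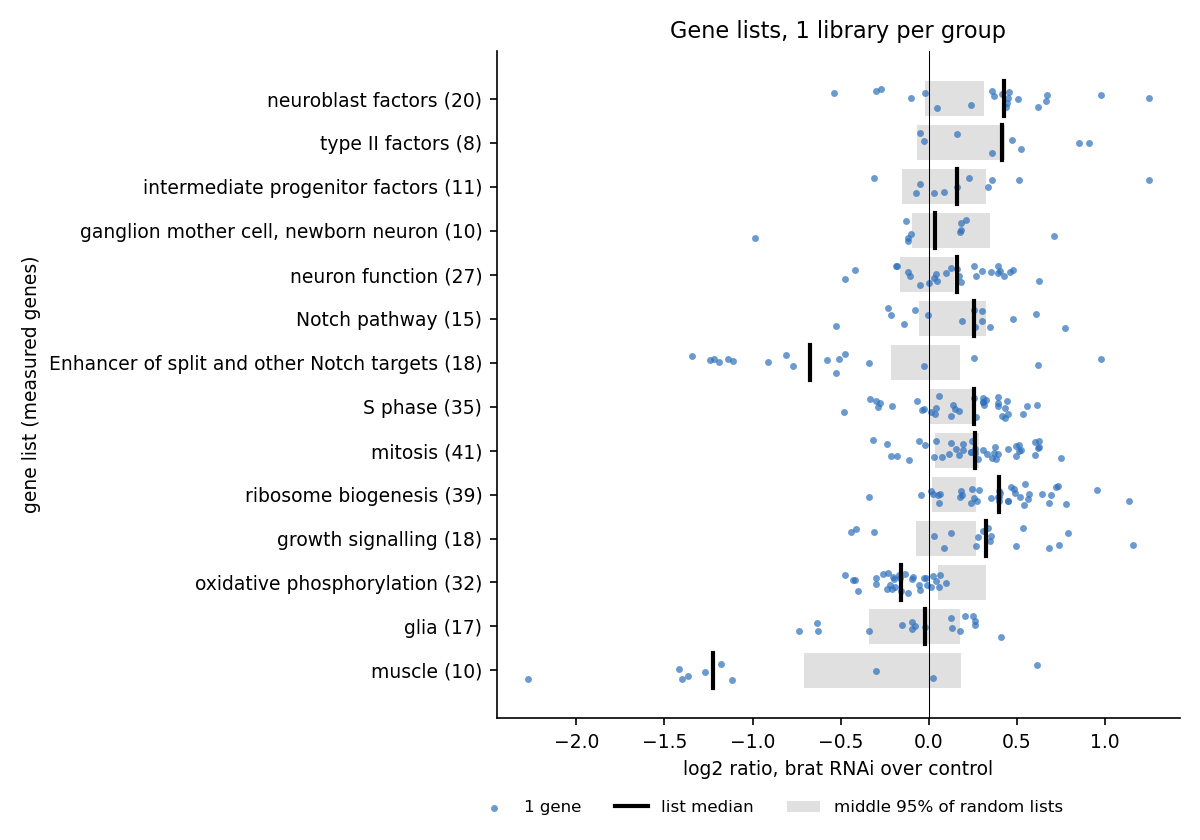
Each blue point is the log2 ratio of brat RNAi over control (x axis) of 1 measured gene in 14 gene lists fixed before the data were examined (y axis, number of measured genes in parentheses). Black bars are list medians and grey boxes the middle 95% of medians of 10000 random lists matched on level. The neuroblast, ribosome biogenesis, growth signalling and neuron function medians (0.43, 0.40, 0.32 and 0.16) lie above their boxes. The Enhancer of split, oxidative phosphorylation and muscle medians (-0.67, -0.16 and -1.22) lie below theirs.

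Neuronal genes gave no large difference. The 27 neuron function genes had a median of 0.16 (0.06 to 0.23, percentile 98.8), with Csp at 0.00 and unc-13 at 0.46, and the 27 axon guidance and adhesion genes 0.19 (0.12 to 0.27, percentile 88.1), with Nrg at 0.08 and Ten-a at 0.29. No member of either was 2-fold apart. With matching on length these percentiles were 61.6 and 10.9, and the medians after correction for length and level were 0.02 and -0.10. Among 14 temporal identity factors (median 0.40, 0.19 to 0.54, percentile 99.8), Eip93F was higher, and hb (-1.99, interval upper limit -0.40, 19 and 4 counts) and pdm2 (-1.17, -2.38 to -0.08, 27 and 10 counts) were lower. With matching on length that percentile was 93.6, and the corrected median was 0.17.

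The list of asymmetric fate and TRIM-NHL genes, 7 measured and with brat among them, had a median of 0.37 (percentile 92.8), a mean of -0.18 and a corrected median of 0.03. In it mei-P26, a TRIM-NHL relative of brat, was higher at 1.15 (1.07 to 1.23) and at 0.77 after correction. The gene nos was lower at -3.26 (-5.20 to -1.81) on 46 and 4 counts. The germline genes BicC (87 and 2 counts) and osk (33 and 0) were also far lower, and whether nos shares their source was not tested. The 18 chromatin regulators studied in type II lineages had a median of 0.21 (percentile 59.5) and -0.03 after correction. Among them osa was at 0.51 and brm at 0.20, and none was 2-fold apart. The 13 apoptosis genes had -0.15 (percentile 15.2), with skl lower at -1.04 (-1.95 to -0.20; -0.75 after correction) on 42 and 17 counts, th at -0.12 and Iap2 at 0.51.

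Some lists of other cell types lay apart from the random lists. The 10 muscle genes had a median of -1.22 (-1.47 to -0.80, percentile 0.010), and 7 were at least 2-fold lower, among them Mlp60A (-2.27, upper limit -0.89), Act57B (-1.41), Act87E (-1.40) and Mlc1 (-1.37), all with under 200 counts. After correction the muscle median was -0.86, and Mlc1 (-0.79), Mlc2 (-0.93) and Tm2 (-0.74) were under 2-fold. The 11 photoreceptor and eye disc genes had 0.40 (0.15 to 0.65, percentile 99.9), with so at least 2-fold higher (1.30, 1.05 to 1.55) and eya and svp at 0.65 and 0.62. The gene svp is also one of the temporal identity factors listed above. The optic lobe factors bsh (-1.70, -2.06 to -1.36) and tup (-1.08, -1.45 to -0.72) were lower, in a list of 12 with a median of 0.10 (percentile 84.7), a mean of -0.16 and a corrected median of -0.06. The fat body genes Lsp1beta (-1.89, -2.77 to -1.09) and Rfabg (-1.14, -1.92 to -0.41) were lower and Fbp1 (1.26, 0.03 to 2.60) higher, all on under 80 counts, in a list of 5 measured genes with a median of 0.16 (percentile 87.7), a mean of -0.15 and a corrected median of -0.13. Glia (17 genes, median -0.02, percentile 66.6), mushroom body (8 genes, 0.08, percentile 68.2), hemocyte (12 genes, -0.07, percentile 19.3) and tracheal or epithelial genes (9 genes, 0.07, percentile 67.9) lay within the middle of the random lists. Their medians after correction were 0.02, -0.11, -0.07 and -0.10. Among them, He in the hemocyte list was at least 2-fold lower (-1.32, -2.01 to -0.68, and -0.85 after correction). In the tracheal or epithelial list vvl was 2.64-fold higher (log2 interval 1.24 to 1.56). Of the most abundant members, Eaat1 was at 0.18 and nrv2 at -0.15, and rut at 0.21 and Fas2 at 0.19. Hml was at 0.48 and CG8193 at -0.09, and shg at 0.68 and uif at 0.22. In the control and brat RNAi library, Eaat1 had 6550 and 6191 counts and Hml 4325 and 5039. The glial gene repo had 138 and 108. Ratios alone do not show how pure the sort was.

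The lowest ratios at a mean normalised count of at least 100 included yolk protein and egg genes. The antifungal peptide gene Drs had 584 counts in the control and 2 in the brat RNAi library (-7.93, -10.98 to -6.07), and dhd, a thioredoxin of the female germline, had 958 and 4 (-7.64, -9.52 to -6.28). Cyp4p2, with 219 and 1 counts, was at -7.51 (-12.82 to -5.02), Yp2, with 525 and 3, at -7.19 (-9.47 to -5.63), Yp1 at -6.31 (-7.37 to -5.42), CG18628 at -5.04, CG6362 at -4.31 and Yp3 at -4.18. The yolk receptor gene yl had 211 and 11 counts, with a log2 interval of -5.02 to -3.13. CG43134 had 226 counts in the control and 0 in the brat RNAi library, which is at least 62.8-fold lower against the floor of 3 counts, with a counting interval reaching -5.66 on the log2 scale.

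Stress, sex and transgene-related genes were set beside these. The 21 heat shock and stress genes had a median of 0.11 (percentile 65.2) and -0.01 after correction, with Hsp70Ab and Hsp70Bb (1.10, and 0.95 after correction) at least 2-fold higher, both of them near-identical copies. The 5 genes of dosage compensation and sex determination had -0.11 (percentile 13.5), with roX1 at 0.42 and Sxl at 0.20, and none was 2-fold apart. Of the 4 transgene-related genes, w was higher and Dcr-2, which both crosses carried as a transgene, was at 0.85 (0.83 to 0.87); the median was 0.65 (percentile 99.6). After correction Dcr-2 was at 0.40 and the median at 0.33.

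The ratio followed transcript length and level. Across 8896 measured genes, which are not independent replicates, Spearman's rho with length was 0.41 and with mean normalised count 0.40. The median log2 ratio went from -0.24 in the shortest decile of genes to 0.32 in the longest, and from -0.44 in the least abundant decile to 0.20 in the most abundant. After correction for both, brat was at -1.15, dpn at 0.83, zld at 0.40 and Myc at 0.76.

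**Figure D3:**
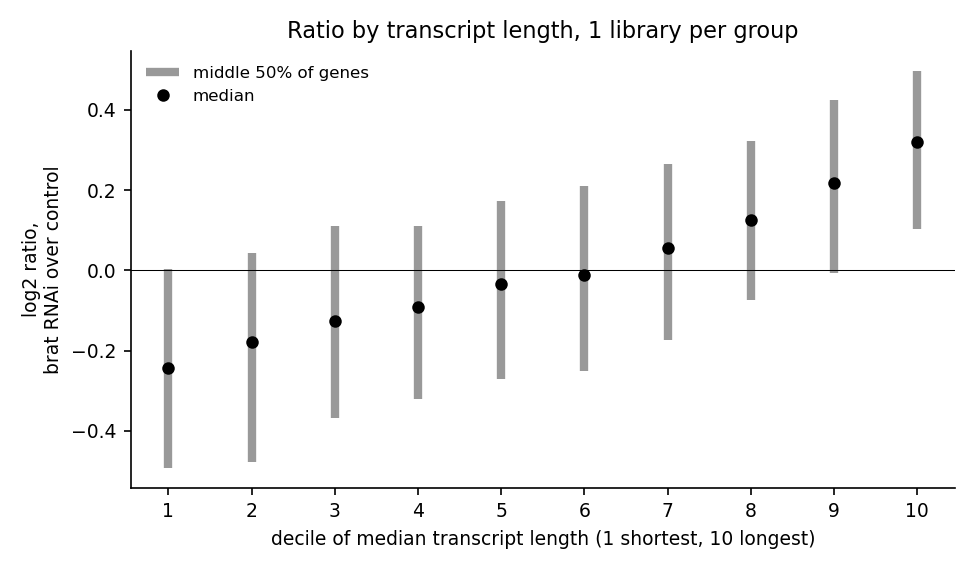
Points are the median log2 ratio of brat RNAi over control (y axis) of measured genes in 10 equal groups by median transcript length (x axis, shortest to longest), and grey bars the middle 50% of genes. The median goes from -0.24 in the shortest to 0.32 in the longest group.

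In the authors' deposited table, 49 genes had an adjusted p under 0.05, 14 higher and 35 lower in the brat RNAi library, and those p-values rest on 1 library against 1. All 49 of those genes in the authors' deposited table were also at least 2-fold apart here. Since the finite fold changes in it equal those computed here, this is no independent check. The authors' deposited table gave an adjusted p of 0.465 for dpn, 0.161 for dm and 0.0770 for grh, and 1 for brat and vfl.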

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

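The tests of explanations in this part were all chosen after the results were seen. The share of read pairs assigned to no annotated feature, which enter no comparison, was 26.6% of the brat RNAi table against 22.0% of the control table. It is given because it lay above the control level; with 1 library per group it cannot be said whether a gap of this size is unusual.

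The genes w, y and CG43182 stood far above their neighbours. The 5 measured genes on each side of w and of y, 20 in all, had a median log2 ratio of -0.090 and a highest of 0.77, which argues against a change over the whole neighbourhood. CG43182 lies directly beside y. A candidate explanation is that an RNAi transgene or its landing site carried w and y as marker genes, with CG43182 in the same fragment. The labels do not give the markers of the line, and an effect of brat itself on these genes stays open.

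Yolk, eggshell and female germline genes were higher in the control library. In a list of 36, made after Yp1, dhd and others had been seen, 32 were measured, with a median of -2.51 and 26 at least 2-fold lower in the brat RNAi library. Outside the 10 lowest genes that prompted the list, 27 members still had a median of -2.12. They come from the same data and are not independent support. A small amount of ovary RNA in the control library is a candidate explanation. However, 6 members, vas, aub, piwi, png, dec-1 and Fcp3C, were not counted as 2-fold lower and bcd had 0 counts in both. The median after correction for length and level was -2.09, which argues against that trend as the whole cause. Both libraries were made from cells of larval brains, so ovary RNA would be foreign to the tissue. Sorting for GFP would be meant to remove other cells, where the RNA came in is not known, and an effect of brat stays open.

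The Enhancer of split and Bearded genes are short, and short genes had lower ratios in general. Random lists matched on length and level had uncorrected medians centred on -0.23, with a 2.5th percentile of -0.46. The uncorrected median of the 14 members of both families, -0.86, lay below that limit, which argues against the trend as the whole cause. After correction the median of the families was -0.57, with all 14 members below 0. Lower mRNA of the Notch receptor is argued against as well, since N was at 0.77. Lower Notch activity in the sorted cells, a different mix of cells in the sort and a difference between the libraries all stay open, and none of these was tested. Of the lists of other tissues, muscle (-1.22), ring gland (-1.74) and ovary (-2.51) had lower medians too, while photoreceptor and eye disc genes had a higher one (0.40, and 0.47 after correction).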

How the results depend on the processing

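The alternatives with a mean count of 100, the correction for length and level, the matching on length and level and the omission of marker and other-tissue genes were chosen after seeing the data. Of the main values, 105 genes higher and 410 lower, those under TMM factors, upper quartile scaling, a pseudocount of 1, no filter, the authors' fold changes and the omission just named stayed within 1.5 times. The authors' finite fold changes equal the ratios computed here, so that alternative differs only in leaving out the interval and the floor. Total count scaling gave 62 higher genes, and a pseudocount of 10 gave 63 and 231. Counts summing to at least 100 gave 57 and 99, a mean of at least 100 gave 51 and 37 (58.0% higher), and the correction 188 and 237 (44.2% higher). A threshold of 1.5-fold gave 542 and 761, one of 4-fold 14 and 142, and the whole interval beyond 2-fold 42 and 122. Fewer genes pass a stricter filter or threshold by construction, and the correction partly evens out higher and lower genes by construction. Otherwise the cause was not tested. Total count and upper quartile scaling moved all ratios by -0.14 and -0.11. They put brat at -0.83 and -0.80, dpn at 0.84 and 0.87 and zld at 0.71 and 0.75, and the correction put them at -1.15, 0.83 and 0.40, each in its main direction. Among 121 named genes, 17 ratios whose interval excluded 0 changed sign under some alternative, none of them 2-fold apart and none above 0.40 in size. Of the 29 fixed lists, 7 lay above and 3 below the middle 95% of random lists, and with no matching 12 lay above. Over all lists and alternatives, 213 list medians stayed within their counting interval and 84 moved out of it, mostly under those scalings and the correction. The sign of the median changed in 11 of 33 lists under the correction. These were axon guidance, Notch pathway, intermediate progenitor, newborn neuron, chromatin, glia, optic lobe, mushroom body, fat body, trachea and heat shock genes. The sign changed in 14 lists under some alternative, none of them outside the middle 95% of random lists matched on level alone. Under other matchings some lay outside, such as the newborn neuron list at the 2.14th percentile with matching on length. Of 64 named genes at least 2-fold apart with a corrected value, 19 fell under 2-fold with it. No paired analysis was possible because each group holds 1 library, and for that reason no library could be left out. Depth limits the scarce genes most, since 2385 measured genes had a mean under 100.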

Other observations

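The genes and lists in this part were chosen after their values were seen. Among abundant genes, stau (1.09, 1.06 to 1.12), Src64B (1.11, 1.03 to 1.19) and clu (1.15, 1.08 to 1.21) were at least 2-fold higher in the brat RNAi library; stau encodes an RNA-binding protein that localises mRNAs. After correction for length and level they were at 0.63, 0.97 and 0.69, all under 2-fold. The stress-responsive noncoding RNA Hsromega was lower at -0.90 (-0.97 to -0.83), and at -1.14 after correction.

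Of 14 measured ecdysone receptor and response genes, 12 were above 0, with a median of 0.45 (0.37 to 0.55). The list was made after Eip93F had been seen among the highest genes, so no rank among random lists is given. Eip93F (1.42) and Eip74EF (1.05) were at least 2-fold higher. After correction for length and level the median was 0.19, with Eip93F at 1.06 and Eip74EF at 0.92.

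Ring gland genes of hormone synthesis were lower in the brat RNAi library. The 11 measured members had a median of -1.74 (-2.16 to -0.84), and 6 were at least 2-fold lower, among them jhamt (-3.93, -5.84 to -2.51), Cyp6g2 (-3.71), spok (-2.28, -3.82 to -1.02) and phm (-2.11), while dib was at 0.37. Of 26 measured neuropeptide genes, with a median of -0.30, 6 were at least 2-fold lower, among them IFa (-2.24), Dh31 (-1.92) and burs (-1.71). After correction for length and level the neuropeptide median was -0.21, at the 22.8th percentile of random lists matched on both, and Dms (-0.82), Pdf (-0.95) and Ccap (-0.64) were under 2-fold. The eclosion hormone gene Eh went the other way, with 2 counts in the control and 69 in the brat RNAi library (5.37, 3.46 to 8.44). In the germline list, BicC had 87 and 2 counts (-5.18, -8.25 to -3.29), and osk had 33 and 0, at least 9.18-fold lower against the floor of 3 counts, with a counting interval reaching -2.82 on the log2 scale.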
